A study of Homo sapiens with 7 samples.

How the data were processed

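Total RNA of U2OS cells was profiled 48 h after transfection, with a lipid reagent, of a synthetic negative-control miRNA (4 arrays) or miR-101 (3 arrays), per the labels' protocols. RNA was extracted with Trizol, amplified and labelled with Cy3 with a low-input one-colour kit and spike-in RNAs, per the labels. Each array was one Agilent one-colour whole-genome array. The authors extracted the signals with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited scanner files hold, per the file headers, a processed intensity per spot (background-subtracted and spatially detrended within the array, with no normalisation between arrays), raw median intensities of spot and local background, and 0/1 marks of spot quality, which are other values than measurements. The table of the whole series holds a deposited intensity per probe, on a linear scale. Its column medians were 207.3 in 6 arrays and 207.4 in control replicate 4, all columns had the maximum 433500, and they correlated with the scanner values of the same arrays at r from 0.9989 to 1.00. Scale and direction were read from this comparison. How the columns were brought to equal quantiles is not given in the sources used here.

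The main values were log2 of the processed intensity minus the 75th percentile of this log2 value over the array's non-control spots. Spots marked as non-uniform or population outliers were dropped, and the 10 spots of each of 999 replicated probes were averaged. The files give probe names and transcript accessions but no gene name column, so that accessions were matched, without versions, to a RefSeq gene table (assembly GRCh38.p14, used only for names and for which genes neighbour each other, since the array headers name hg19). Of 25863 probes with a RefSeq transcript accession, 24910 matched, giving 19102 symbols. Other probes were kept under their accession or probe name. The probe with the highest mean signal over all 7 arrays stood for a gene. A probe was tested if it was well above background on every array of at least 1 group, which left 26380 of 34127 probes and 21418 genes, 15907 with a symbol and 5511 without. Among the tested genes 113 single values were missing.

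Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off, two-sided, median moderated degrees of freedom 7.30), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every adjusted p of a gene is from this limma fit, and every adjusted p of a list is from limma's camera unless another test is named. The sample table was read with jsonlite 2.0.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The 25 gene lists (623 entries, 622 of them matched to a current symbol) were tested with camera at a correlation between genes of 0.01 and adjusted over the lists. An estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, and compares the list with no other genes. Lists had to have at least 5 tested members. They were published miR-101 targets, proteasome genes, immunoproteasome and activators, p53 targets, G1/S and replication, G2/M and mitosis, PRC2, heat shock, unfolded protein response, interferon, NF-kB and inflammatory, immediate early, BCL2 family, autophagy and lysosome, cholesterol synthesis, glycolysis and hypoxia, matrix and adhesion, ribosomal proteins, oxidative phosphorylation, miRNA pathway, double-strand break repair, osteoblast lineage, and epithelial, blood and immune, and endothelial markers.

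The groups, the test, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 largest falls and the 12 largest rises among called genes that were well above background on all 7 arrays, had separate groups and had a gene symbol, 9 genes of prior interest, up to 4 members of each list with the smallest p, and up to 3 genes per direction with the largest bound. It gave 123 named genes besides the bounds. The control pair with the smallest variance of differences was to be averaged as the repeated sample if the next pair's variance was at least 1.5 times larger. This was not met, so all 4 control arrays entered separately. The 3 experiments are called independent in the series design, but 2 control arrays share 1 RNA and nothing ties the control arrays to the miR-101 arrays, so that p-values measure the spread between these arrays. The slide numbers in the file headers gave the same batches as the scan runs, and slides 1, 2 and 4 held both groups.

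Alternatives were quantile normalisation, median centring, normexp background correction with an offset of 50 followed by quantile normalisation, the series table, no filter on dim probes, only probes above background on all arrays, the mean of a gene's probes, trend and robust moderation, averaging of each control pair, a replicate block, the slide as a block, leaving out each array, stricter thresholds (0.01, or a log2 change of at least 1), an estimated correlation, fry and, added after the data were seen, array weights. For normexp the median spot signal stood in for the mean signal, which the files used here do not hold. A test of miR-101 seed sites in 3′ untranslated regions was planned and not run, since no transcript sequence was used here. Some genes that the naming rule selects are not reported here. No coordinates are given, because the gene table and the array annotation name different builds. The scripts were tested on simulated data made from the real arrays' spread: of 200 changed genes among 21311, 37 of 100 with a log2 change of 1 and 65 of 100 with a log2 change of 2 were recovered at 4 against 3 arrays with 2 false calls. Without control replicate 4, 62 and 86 were recovered with 11 false calls. The simulated genes varied independently, each with the same spread on all arrays, and the G2/M list was also shifted in the first run. Far fewer genes were changed than were called in the real data, so that these rates need not hold there.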

Results

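Gene expression was measured in U2OS cells, a human osteosarcoma line, 48 h after transfection with a synthetic negative-control miRNA or with synthetic miR-101, a small RNA that represses mRNAs carrying sites for it. The control group held 4 one-colour microarrays and the miR-101 group held 3. The series design gave 3 independent experiments and stated that 1 control sample had been placed on 2 arrays, without saying which. The 75th percentile of the probe intensities, which served as the measure of depth, ranged from 2242 to 2960 on 6 of the 7 arrays and was 1333 on control replicate 4. Between 72.3% and 82.0% of 34127 probes were well above background on each array, and 0 spots were saturated. The number of arrays and the spread of control replicate 4 limited the precision.

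Control replicate 4 stood apart from the rest of its group. The SD of the log2 differences between this array and the other control arrays was 0.86 to 0.89, against 0.30 to 0.39 among the other 3 control arrays and 0.25 to 0.33 among the miR-101 arrays. Control replicates 2 and 3 had the smallest variance of differences (0.0918), but the next pair was only 1.45 times as high, under the ratio of 1.5 that had been set for taking a pair as the repeated sample. All 4 control arrays therefore entered the comparison separately, although 2 of them hold the same RNA. When each of the 6 possible pairs was averaged in turn, 2664 to 5817 genes changed. The pairs with control replicate 4, which differed most from the others, gave 5249 to 5817, and the remaining pairs 2664 to 2866. The distance of control replicate 4 argues against its being in the repeated pair, which favours the range of 2664 to 2866.

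**Figure D1:**
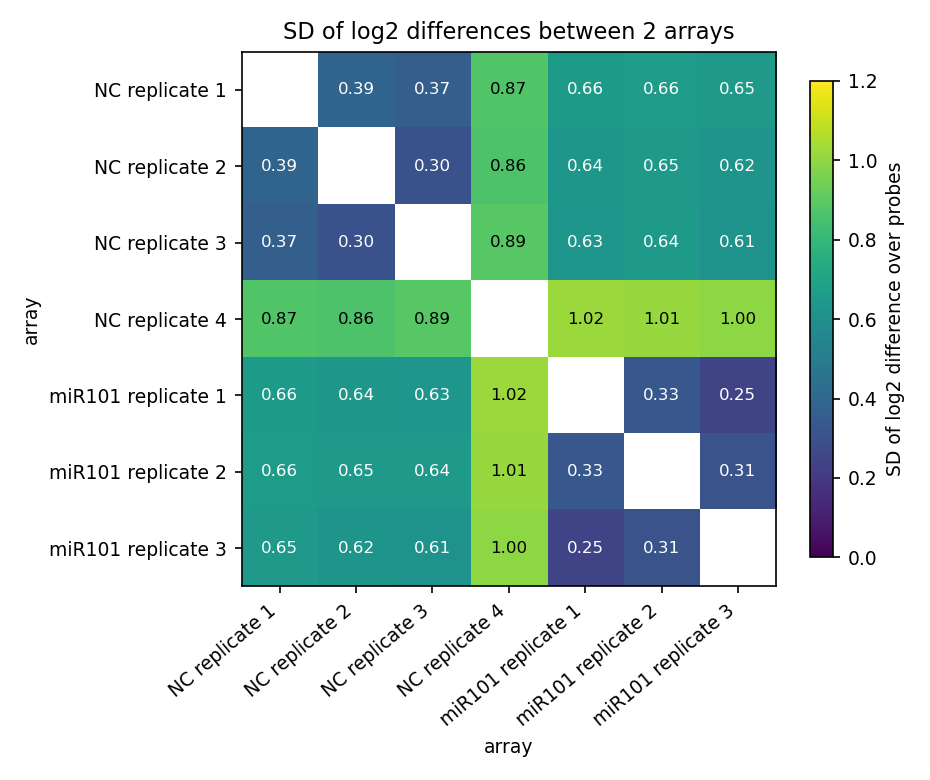
Matrix of the SD over probes of the log2 difference between each pair of the 7 arrays, with control (NC) and miR-101 arrays on both axes and the SD printed in each cell. Control replicate 4 differed from the other control arrays with an SD of 0.86 to 0.89, while the other control pairs lay between 0.30 and 0.39.

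The comparison between the groups asked which genes change when miR-101 is raised in these cells. STMN1, which encodes the microtubule-destabilising protein stathmin, fell by 2.59 ± 0.19 on the log2 scale (SE, n = 4 control and 3 miR-101 arrays). POMP, an assembly chaperone of the proteasome core, fell by 2.07 ± 0.32 (SE). IL1B, which encodes an inflammatory cytokine, rose by 5.59 ± 0.15 and CSF2, which encodes a growth factor of myeloid cells, by 4.98 ± 0.21 (SE). The inducible heat shock gene HSPA6 rose by 4.62 ± 0.24 (SE), and EZH2, the catalytic subunit of the polycomb repressive complex PRC2 and a published miR-101 target, had a log2 change of -0.13 ± 0.22 that did not pass the test (adjusted p = 0.72).

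Of 21418 genes tested with limma, 1457 were lower and 2126 higher in miR-101 cells, 3583 in all. The balance of directions depended on the scaling, since quantile normalisation gave 1780 lower and 1909 higher genes. Of the 3583 genes of the main fit, 611 were at least 2-fold lower and 1226 at least 2-fold higher. The groups did not overlap in the 3570 called genes with values on all 7 arrays (the other 13 lacked a value), nor in 37.4% of all tested genes with such values. The arrays lay on 4 slides, of which slides 1, 2 and 4 held both groups. With the slide as a block, which takes control replicate 3, alone on slide 3, out of the estimate, 323 genes were lower and 791 higher, 1114 in all. Without control replicate 4, 3752 were lower and 4630 higher (8382 in all), of which 695 and 1485 by at least 2-fold, and 1455 of the 1457 lower and 2124 of the 2126 higher genes kept their calls. The SD of differences between control replicate 4 and the other control arrays (0.86 to 0.89, against 0.30 to 0.39 among those) argues against its holding the repeated RNA. With the repeated sample among control replicates 1 to 3, these arrays hold fewer distinct RNAs than arrays. Every p-value without control replicate 4 then rests partly on 1 RNA measured again. Leaving out miR-101 replicate 1, 2 or 3 gave 1674, 1868 or 1732 changed genes, and leaving out control replicate 2 gave 933 lower genes. Of the 95 named genes that were called, 57 kept their call whichever array was left out and 49 kept it with the slide as a block. Another scaling, background, filter or probe setting ended the calls of 24 of them (adjusted p from 0.0501 to 0.82): MCL1, PSG2, PSMA4, FOXM1, SFN, ZMAT3, AEBP2, JARID2, XPO5, XRCC4, ASNS, TRIB3, BMF, MAP1LC3B, GABARAPL2, LSS, INSIG1, HK2, NDUFA9, RPL22, COL1A2, EPCAM, KDR and PECAM1. With normexp background correction, whose offset draws dim signals together, 28 of the 95 had changes more than 1.5 times smaller, among them ECM2 (-2.53), IL1B (3.69), HSPA6 (2.93), POMP (-1.28) and CDH1 (-0.74), and 24 of the 28 were still called. Averaging control replicates 1 and 2, 1 and 3, or 2 and 3 ended the calls of 20, 17 or 19 named genes. Averaging control replicate 4 with 1, 2 or 3 instead added calls of 14, 10 or 11 named genes.

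The genes with the largest falls encode proteins of several kinds. ECM2, a matrix protein gene, fell by 5.02 ± 0.18 (SE, adjusted p = 7.7e-05), from a normalised log2 signal of -2.13 ± 0.28 in control to -7.15 ± 0.12 in miR-101 cells (SD, n = 4 and 3), with -5.15, -4.90 and -4.64 within slides 1, 2 and 4. FGF21, a secreted metabolic hormone, fell by 4.37 ± 0.39, and CSRP3, a muscle LIM protein, fell by 3.48 ± 0.28. The changes of RAB39B (a Rab GTPase), FUT1 (a fucosyltransferase), MFAP4 (a microfibril-associated protein) and NAT16 were -3.34, -3.10, -2.80 and -3.40. Those of the nuclear import receptor KPNA7, the smooth muscle calponin CNN1, the platelet collagen receptor GP6 and the pregnancy glycoprotein PSG2 were -2.78, -2.66, -2.60 and -2.60. The call of PSG2 was the exception in this set, since it ended when any array but control replicate 4 was left out (highest adjusted p = 0.14) and with the slide as a block (adjusted p = 0.067).

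The genes with the largest rises included several that encode cytokines and chemokines. IL1B rose from -5.98 ± 0.14 to -0.39 ± 0.20 (SD, n = 4 and 3; adjusted p = 2.9e-05), and by 5.64, 5.59 and 5.34 within slides 1, 2 and 4. CSF2 rose by 4.98, and the neutrophil chemokines CXCL3, CXCL8 and CXCL2 rose by 4.89 ± 0.45, 4.79 ± 0.90 and 4.09 ± 0.27 (SE). IL1RN, which encodes an antagonist of the interleukin 1 receptor, rose by 4.05, although a second probe of the gene gave 0.02 and the mean of its probes 2.03. The keratin KRT6A rose by 4.87 and the salivary protein gene PRB2 by 4.26. SERPINB4, FRG2 and FRG2C rose by 6.27, 5.87 and 5.46, but each has near-identical copies in the genome, so that the gene behind these probes is uncertain. CXCL8 lay at -3.62 in control replicate 4 against the other control arrays, its rise without that array was 3.89, and its call ended when any miR-101 array was left out (highest adjusted p = 0.055).

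**Figure D2:**
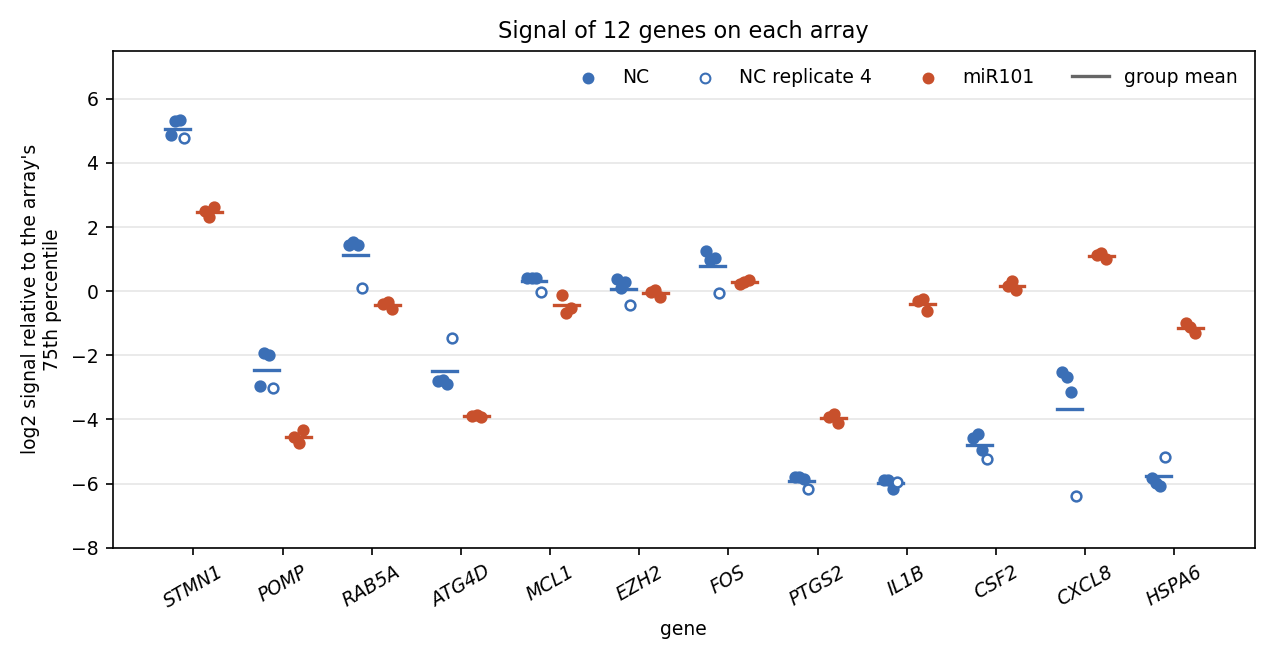
Normalised log2 signal (vertical axes, relative to the 75th percentile of each array) of 12 genes on each control (NC) and miR-101 array, as dots with bars at the group means and control replicate 4 drawn hollow. STMN1 fell from 5.07 to 2.47 and IL1B rose from -5.98 to -0.39, while EZH2 lay at 0.08 and -0.05.

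Published miR-101 targets fell more often than they rose. Of 35 tested genes on this list, 12 fell and 1 rose, and 15 fell and 5 rose when adjusted over the list alone. STMN1 fell (adjusted p = 0.00035; log2 change -1.60 with the mean of its probes), as did the atypical chemokine receptor ACKR3 by 1.72 ± 0.18, the DNA methyltransferase DNMT3A by 1.28 ± 0.14 and the anti-apoptotic gene MCL1 by 0.75 ± 0.19 (SE). PTGS2, the inducible prostaglandin synthase, rose by 1.95 ± 0.15 (adjusted p = 0.00039). FOS had a log2 change of -0.51 ± 0.30 (adjusted p = 0.31) and MYCN, well above background on 3 of the 4 control arrays, of 1.56 ± 0.56 (adjusted p = 0.11). Without control replicate 4, FOS was called at -0.80 (adjusted p = 0.0014), MYCN at 0.99 (adjusted p = 0.00018) and EZH2 stayed uncalled at -0.31 (adjusted p = 0.063). Array weights, added after the data were seen, called EZH2 lower at -0.29 (adjusted p = 0.046). Among the control arrays they gave most weight to replicates 2 and 3 (2.75 and 1.40). This pair had the smallest variance of differences and may hold 1 RNA, which would understate the spread. The early endosome GTPase RAB5A fell by 1.56 ± 0.36 and the autophagy protease ATG4D by 1.41 ± 0.35 (SE). The calls of RAB5A, ATG4D and MCL1 ended with the slide as a block (adjusted p = 0.073, 0.076 and 0.15). They also ended for RAB5A without any array but control replicate 4 (highest adjusted p = 0.099), for ATG4D without control replicate 1 or 2 or any miR-101 array (highest 0.11), and for MCL1 without control replicate 1, 2 or 3 or miR-101 replicate 2 or 3 (highest 0.14).

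The median log2 change of the published targets was -0.39 (camera adjusted p = 0.0058; adjusted p = 0.83 with an estimated correlation). It was -0.49, -0.49 and -0.04 within slides 1, 2 and 4 and -0.38 with the slide as a block (adjusted p = 0.033). The list lay at -0.44 in control replicate 4 against the other control arrays, and without that array 21 targets fell, 5 rose and the median was -0.52 (adjusted p = 0.00026 at the preset correlation; adjusted p = 0.20 with an estimated one). POMP had been placed on this list and on the proteasome list from memory of related work, so that its fall is not independent evidence for either list if it was picked from these arrays. The other members were set from general knowledge before the data were examined. Whether any of them was picked from these arrays was not checked.

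Among the proteasome genes, POMP fell while subunit genes were mostly above 0. POMP went from -2.47 ± 0.59 to -4.54 ± 0.20 (SD, n = 4 and 3; adjusted p = 0.0054), with -1.78, -2.60 and -1.33 within slides 1, 2 and 4 and -1.90 with the slide as a block (adjusted p = 0.040). Of 40 proteasome subunit and assembly genes, 1 fell (POMP) and 2 rose, also when adjusted over the list alone. PSMD11, a subunit of the regulatory particle, rose by 1.06 ± 0.18, and PSMA4, a core subunit, by 0.67 ± 0.14 (SE), but neither call held with the slide as a block (adjusted p = 0.065 and 0.15), and that of PSMA4 ended without any of the miR-101 arrays (highest adjusted p = 0.096). The list's median was 0.25 (camera adjusted p = 0.046; adjusted p = 0.83 with an estimated correlation), 0.32, 0.16 and 0.36 within slides 1, 2 and 4, and 0.24 with the slide as a block (adjusted p = 0.046). The list lay at -0.21 in control replicate 4 against the other control arrays, and without that array 17 genes rose, 3 fell and the list was no longer called (0.23, adjusted p = 0.065). Its call also ended without miR-101 replicate 2 or 3 (adjusted p = 0.061 and 0.10). Of 7 immunoproteasome and activator genes, 1 rose, also when adjusted over the list alone: PSMB9 by 0.81 ± 0.14 (SE; camera adjusted p of the list = 0.99), and its call ended with the slide as a block (adjusted p = 0.097). Leaving out control replicate 4 gave 2 lower and 2 higher genes of this list.

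NF-kB and inflammatory genes had the largest median log2 change of the lists, 1.34 (camera adjusted p = 2.4e-10 at the preset correlation; adjusted p = 0.18 with an estimated one). Of 22 tested genes, 16 rose and 1 fell, and 19 rose and 1 fell when adjusted over the list alone. CXCL1, a neutrophil chemokine, rose by 3.07 ± 0.17 (SE) beside IL1B, CXCL2 and CXCL3. A second probe of CXCL1 gave 0.22, but it was too dim to pass the filter for testing. The member that fell, named after its values were seen, was the interleukin 6 family cytokine LIF, by 1.43 ± 0.14 (SE, adjusted p = 0.00080). The list's median was 1.35, 1.13 and 1.13 within slides 1, 2 and 4, and 1.16 with the slide as a block (adjusted p = 5.4e-10). Control replicate 4 differed from the other control arrays by 0.02 over this list, and without it 20 genes rose and 1 fell.

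**Figure D3:**
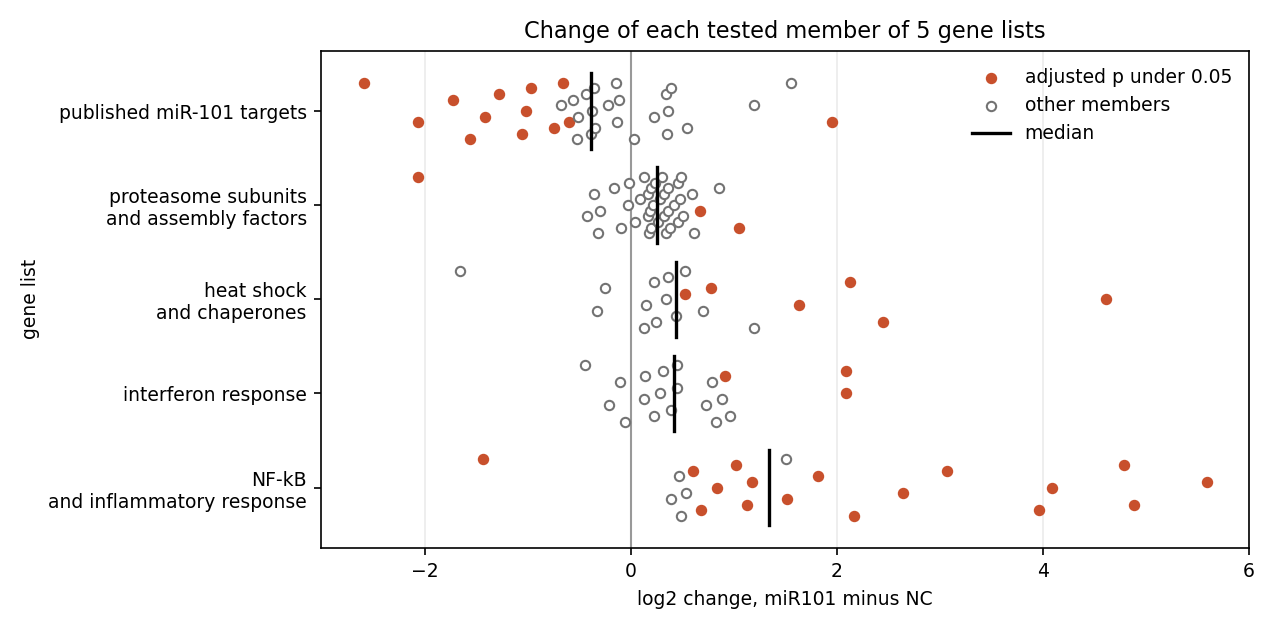
Log2 change in miR-101 against control cells (horizontal axis) of each tested member of the 5 lists called by camera at the preset correlation (0 were called with an estimated one), with filled points for members with an adjusted p under 0.05 and a black line at each list's median. The medians were -0.39 for published targets, 0.25 for proteasome, 0.44 for heat shock, 0.42 for interferon and 1.34 for NF-kB genes.

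The heat shock and chaperone list had a median of 0.44 and was called by camera at the preset correlation (adjusted p = 0.0058) but not with an estimated one (adjusted p = 0.18). Of 19 tested genes, limma called 6 higher and 0 lower, also when adjusted over the list alone (1 was lower at an unadjusted p under 0.05). HSPA6 rose, although a second probe of it gave 1.36, and the HSP70 genes HSPA1A and HSPA1B, which are near-identical and cannot be separated with certainty, rose by 2.45 ± 0.26 and 2.13 ± 0.19 (SE). The co-chaperone BAG3 rose by 1.64 ± 0.32 (SE), a call that ended without any of the miR-101 arrays (highest adjusted p = 0.065) and with the slide as a block (adjusted p = 0.065). The list's median was 0.38, 0.36 and 0.82 within slides 1, 2 and 4, and 0.49 with the slide as a block (adjusted p = 0.0050). Its value in control replicate 4 was -0.32 against the other control arrays, and without that array 10 genes rose and 1 fell. The member that fell, named after its values were seen, was the small heat shock gene CRYAB, which stood at -1.66 ± 0.61 with all arrays (SE, adjusted p = 0.12) and at -1.05 without control replicate 4 (adjusted p = 0.00053).

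The interferon response list had a median of 0.42 and was called by camera at the preset correlation (adjusted p = 0.023) but not with an estimated one (adjusted p = 0.83) or with fry (adjusted p = 0.19). Of 20 tested genes, limma called 3 higher and 0 lower, and 6 higher when adjusted over the list alone (8 were higher and 0 lower at an unadjusted p under 0.05). IFIH1, a sensor of double-stranded RNA, rose by 2.09 ± 0.19, and IFIT2, an interferon-induced RNA-binding protein, by 0.92 ± 0.16 (SE), a call that ended with the slide as a block (adjusted p = 0.095). OAS1, which makes a second messenger when it binds double-stranded RNA, was well above background on 3 of the 4 control arrays and rose by 2.09 ± 0.46 (SE), a call that ended without control replicate 1 or 2 or any miR-101 array (highest adjusted p = 0.089). The list's median was 0.59, 0.77 and -0.04 within slides 1, 2 and 4, and 0.37 with the slide as a block (adjusted p = 0.036). The list lay 0.67 higher in control replicate 4 than in the other control arrays, and without that array 13 genes rose and the median was 0.68 (adjusted p = 0.00043 at the preset correlation; adjusted p = 0.58 with an estimated one). Without control replicate 2 the list was not called (0.32, adjusted p = 0.0501).

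The G1/S and p53 lists did not pass camera, and whether the G2/M list passed depended on the setting. Of 36 G1/S and replication genes, 2 fell and 4 rose (2 and 5 when adjusted over the list alone; median 0.23, camera adjusted p = 0.38). The ribonucleotide reductase subunit RRM1 fell by 0.84 ± 0.12 and the transcription factor E2F1 by 0.90 ± 0.17, while the cyclin CCNE1 rose by 0.71 ± 0.12 (SE). Of 31 G2/M and mitosis genes, 1, the mitotic transcription factor FOXM1, rose by 0.44 ± 0.11 (SE), and limma called 0 when adjusted over the list alone (3 were higher and 0 lower at an unadjusted p under 0.05). The call of FOXM1 ended without any array but control replicate 4 (highest adjusted p = 0.15), and that of E2F1 without miR-101 replicate 1 or 2 (highest 0.058). The median of the G2/M list was 0.33 (camera adjusted p = 0.0515 at the preset correlation; adjusted p = 0.997 with an estimated one), and 0.08, 0.08 and 0.83 within slides 1, 2 and 4. At the preset correlation 14 of 23 alternatives called it, among them quantile normalisation (adjusted p = 0.012), normexp (adjusted p = 0.0040), the series table (adjusted p = 0.013) and the slide as a block (0.37, adjusted p = 0.013), none of them tested with an estimated correlation. Its genes lay at -0.77 in control replicate 4 against the other control arrays, and without that array 1 fell, 6 rose and the median was 0.08 (adjusted p = 0.36), while 8 fell and 9 rose of the G1/S genes (median 0.10). Of 29 p53 targets, 2 fell (SFN and ZMAT3) and 2 rose (PMAIP1 and FAS), also when adjusted over the list alone (median -0.04, camera adjusted p = 0.99). The death receptor gene FAS rose by 1.28 ± 0.22 and the BH3-only gene PMAIP1 by 0.96 ± 0.15 (SE), while the call of SFN ended without control replicate 1 or 3 or any miR-101 array (highest adjusted p = 0.13) and that of ZMAT3 without any array but control replicate 4 (highest 0.16). With the slide as a block none of these 8 cell cycle and p53 genes was called (limma adjusted p from 0.059 to 0.22). The p53 targets lay 1.00 higher in control replicate 4 than in the other control arrays, and without that array 4 fell, 9 rose and the median was 0.23 (camera adjusted p = 0.24).

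Stress and signalling lists held calls in both directions. Of 25 unfolded protein response genes, 5 fell and 2 rose (6 and 2 when adjusted over the list alone; median -0.21, camera adjusted p = 0.37, fry adjusted p = 0.038). The lipoprotein receptor VLDLR fell by 1.79 ± 0.18, the glutathione-degrading enzyme CHAC1 by 1.79 ± 0.27 and the asparagine synthetase ASNS by 1.17 ± 0.19 (SE), the last a call that ended without miR-101 replicate 1 or 3 (highest adjusted p = 0.053). Of 22 immediate early genes, 3 fell and 4 rose (7 and 4 when adjusted over the list alone; median -0.42, camera adjusted p = 0.37, fry adjusted p = 0.031). The transcription factor EGR1 fell by 1.69 ± 0.11, whereas DUSP5 and DUSP6, phosphatases that switch ERK signalling off, rose by 1.18 ± 0.14 and 1.53 ± 0.22 (SE). Of 16 BCL2 family genes, 3 fell and 2 rose (3 and 3 when adjusted over the list alone; median -0.25, camera adjusted p = 0.94), with the pro-apoptotic BMF at -1.15 ± 0.18 (SE) among the falls. Of 31 autophagy and lysosome genes, 1 fell (ATG4D) and 4 rose (1 and 5 when adjusted over the list alone; median 0.25, camera adjusted p = 0.28). A second probe of MAP1LC3B, one of the 4, gave -0.68 against 0.58 for the brightest, and its call ended without any array but control replicate 4 (highest adjusted p = 0.13). Further called members included TRIB3 (lower) of the unfolded protein response, IER3 (higher) of the immediate early genes, HRK (lower) and BCL2A1 (higher) of the BCL2 family, and ATG14 and GABARAPL2 (higher) of autophagy. TRIB3 and ASNS stood at -0.32 and -0.75 with the values of the series table (adjusted p = 0.78 and 0.21), and BMF at -0.64 with normexp (adjusted p = 0.058). In the main fit TRIB3 and ASNS had no value on control replicate 2 after marked spots were dropped. Their control means rest on the other control arrays. Calls ended without any of the miR-101 arrays for TRIB3, HRK, BCL2A1, ATG14 and GABARAPL2, and also without control replicate 1 or 3 for TRIB3, 2 for ATG14 and 1 for GABARAPL2 (highest adjusted p = 0.12, 0.070, 0.078, 0.081 and 0.12). With the slide as a block, ASNS, MAP1LC3B, TRIB3, IER3, HRK, BCL2A1, ATG14 and GABARAPL2 were not called (adjusted p from 0.055 to 0.18). Without control replicate 4, 10 fell and 5 rose of the unfolded protein response, 10 and 4 of the immediate early, 4 and 5 of the BCL2 family (median 0.02) and 2 and 8 of the autophagy genes.

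Metabolic and housekeeping lists were not called by camera. Of 23 cholesterol synthesis genes, 2 fell and 3 rose (also when adjusted over the list alone; median -0.06, camera adjusted p = 0.94). Of 25 glycolysis and hypoxia genes, 2 fell and 5 rose (also when adjusted over the list alone; median -0.13, camera adjusted p = 0.99), including the stress-responsive NDRG1 at 1.16 ± 0.13 and the oxygen sensor EGLN3, well above background on 3 of the 4 control arrays, at 2.12 ± 0.30 (SE). The change of EGLN3 ranged from 0.65 to 2.33 over the alternatives that tested it, all of which called it. Of 32 oxidative phosphorylation genes, the ATP synthase subunit ATP5F1B fell by 1.46 ± 0.16 and NDUFA9 rose by 0.46 ± 0.12 (SE), and limma called 1 lower and 0 higher when adjusted over the list alone (2 and 1 at an unadjusted p under 0.05; median 0.01, camera adjusted p = 0.99). The call of NDUFA9 ended when any array but control replicate 4 was left out (highest adjusted p = 0.18). Of 41 ribosomal protein genes, 1 fell (RPL22, by 0.54 ± 0.13, SE), and limma called 0 when adjusted over the list alone (1 was lower and 0 higher at an unadjusted p under 0.05; median -0.08, camera adjusted p = 0.51). The call of RPL22 ended without any array but control replicate 4 (highest adjusted p = 0.12). Further called members included LSS (lower), NSDHL and INSIG1 (higher) of cholesterol synthesis, and HK2 (lower) and ADM (higher) of glycolysis and hypoxia. The calls of LSS and HK2 rested on 1 probe each, since second probes gave 0.33 and 0.04 and the mean of probes -0.36 and -0.27 (adjusted p = 0.44 and 0.38). Calls ended without any of the miR-101 arrays for LSS and HK2, without miR-101 replicate 1 or 2 for NSDHL and without any array but control replicate 4 for INSIG1 (highest adjusted p = 0.088, 0.081, 0.064 and 0.13). With the slide as a block, LSS, NSDHL, INSIG1, HK2, ADM, NDRG1, NDUFA9 and RPL22 were not called (adjusted p from 0.053 to 0.20). Without control replicate 4, 4 fell and 5 rose of the cholesterol (median 0.12), 4 and 6 of the glycolysis (median 0.08), 3 and 2 of the oxidative phosphorylation and 1 and 0 of the ribosomal protein genes (median 0.04), as called by limma.

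Regulators of chromatin, small RNAs and DNA repair moved little as lists. Of 10 tested PRC2 components, RBBP7 and AEBP2 fell (-1.02 and -0.99) and JARID2 rose (0.79), with 2 and 2 when adjusted over the list alone (median -0.05, camera adjusted p = 0.87). Each of these calls ended without any of the miR-101 arrays, and also without control replicate 2 for RBBP7, 1, 2 or 3 for AEBP2 and 2 or 3 for JARID2 (highest adjusted p = 0.077, 0.15 and 0.14). Of 13 miRNA pathway genes, AGO2, the slicing Argonaute, rose by 0.56 ± 0.12, and XPO5, which exports miRNA precursors, fell by 0.51 ± 0.11 (SE), with 3 lower and 1 higher when adjusted over the list alone (median 0.06, camera adjusted p = 0.94). Both calls ended without any of the miR-101 arrays, and also without control replicate 2 or 3 for AGO2 and 1, 2 or 3 for XPO5 (highest adjusted p = 0.089 and 0.10). Of 28 double-strand break repair genes, limma called 1 higher and 0 lower, and 0 when adjusted over the list alone (3 were higher and 2 lower at an unadjusted p under 0.05; median -0.04, camera adjusted p = 0.68). That gene was the end-joining factor XRCC4 (0.43 ± 0.11, SE), whose call ended without any array but control replicate 4 (highest adjusted p = 0.18). With the slide as a block none of these 6 genes was called (adjusted p from 0.10 to 0.24). Once control replicate 4 was left out, 3 fell and 2 rose of the PRC2, 4 and 3 of the miRNA pathway and 6 and 3 of the break repair genes.

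Matrix, lineage and cell type lists were not called by camera either. Of 32 matrix and adhesion genes, 5 fell and 4 rose (5 and 7 when adjusted over the list alone; median -0.15, camera adjusted p = 0.87). N-cadherin, CDH2, fell by 1.06 ± 0.11, the integrin subunit ITGB3 rose by 1.10 ± 0.19 (SE), and COL1A2, well above background on 2 of the 4 control arrays, rose by 1.63, which became 0.21 with normexp (adjusted p = 0.13). Of 10 osteoblast genes, 1 rose and 1 fell (3 and 1 when adjusted over the list alone; median 0.19, camera adjusted p = 0.51, fry adjusted p = 0.031). The growth factor BMP2 rose by 1.61 ± 0.14 and the collagen COL1A1 fell by 1.12 ± 0.27 (SE), the latter a call that ended without control replicate 2 or 3 or any miR-101 array (highest adjusted p = 0.11). Of 13 epithelial markers, 1 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.99). E-cadherin, CDH1, fell by 2.00 ± 0.27 and the keratin KRT19 rose by 1.39 ± 0.22 (SE) beside ELF3 and EPCAM, of which EPCAM lost its call without control replicate 1 or 2 or any miR-101 array (highest adjusted p = 0.13), and the list lay 0.92 higher in control replicate 4 than in the other control arrays. Of 12 blood and immune markers, 2 rose (HBA2, a globin with a near-identical copy, by 3.45, and CD14 by 1.01) and limma called 0 lower, also when adjusted over the list alone (3 were higher and 0 lower at an unadjusted p under 0.05; camera adjusted p = 0.51). The call of CD14 ended without any array but control replicate 4 (highest adjusted p = 0.10). Of 8 endothelial markers, 2 were higher (KDR and PECAM1) and 0 lower by limma, also when adjusted over the list alone and at an unadjusted p under 0.05 (camera adjusted p = 0.63). With the slide as a block, ITGB3, COL1A1, KRT19, EPCAM and CD14 were not called (adjusted p = 0.064, 0.093, 0.052, 0.11 and 0.13). When control replicate 4 was left out, limma called 11 lower and 7 higher of the matrix, 1 and 4 of the osteoblast, 2 and 5 of the epithelial, 0 and 6 of the blood and immune (median 0.39) and 0 and 2 of the endothelial genes. The median, mean and test of a list differed in sign for immunoproteasome (median 0.03, mean 0.03, test down), BCL2 (-0.25, 0.01, down), glycolysis (-0.13, 0.11, up), matrix (-0.15, 0.04, down), oxidative phosphorylation (0.01, 0.01, down), miRNA pathway (0.06, -0.02, down) and break repair genes (-0.04, 0.00, down).

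Some genes were not well above background on any array of a group, and for these only a bound was given. The bound set the mean of the brighter group against the dimmer group's mean of, on each array, the higher of the gene's own signal and the lowest signal among probes well above background. It was computed for 123 genes that were higher and 4 that were lower in miR-101 cells. These counts are not on an equal footing, since a gene entered through all 3 miR-101 arrays or through all 4 control arrays. The control arrays also had fewer probes well above background (72.3% to 80.7%, against 78.3% to 82.0% on the miR-101 arrays). ABHD12B, a member of a hydrolase family, was at least 46.0-fold higher (adjusted p = 0.00036). SERPINB2, an inhibitor of plasminogen activators, was at least 32.0-fold higher (adjusted p = 8.9e-05), and FRG2B, one of several near-identical copies, at least 23.6-fold higher (adjusted p = 0.00058). The vascular receptor KDR was at least 2.33-fold, the endothelial adhesion gene PECAM1 at least 1.54-fold and the epithelial transcription factor ELF3 at least 3.81-fold higher. These bounds hold for the processed intensities only, and with normexp KDR and PECAM1 were not called (adjusted p = 0.13 and 0.19). The call of PECAM1 ended without control replicate 3 or any miR-101 array (highest adjusted p = 0.086). LRRC32, which anchors latent TGF-beta, was at least 6.37-fold lower (adjusted p = 0.0025), and the channel-associated genes ABCC9 and KCNJ5 were at least 5.50-fold and 3.32-fold lower.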

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

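The tests of slide and of RNA content for control replicate 4, of control replicate 4 for the excess of rises, and all 3 tests for the NF-kB genes were chosen after the result was seen. In each group of 4 control arrays, an array was set apart if its gap to the nearest other array was more than 0.829 of the group's range, which chance gives in about 1 in 20 groups. Of 151 values checked, 33 had an array apart, 31 of them control replicate 4 and 2 control replicate 1. The values that follow are the array's log2 signal minus the mean of the other 3 control arrays.

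The median spike-in signal of control replicate 4 was -1.93. Unlike the gene values, it was not scaled to the array's 75th percentile. It therefore includes the lower brightness of the whole array (1333, against 2242 to 2764 on the other control arrays). Among the genes with the largest changes, control replicate 4 differed by 1.00 in CSRP3, 0.32 in FUT1, -0.81 in MFAP4, 1.86 in KPNA7, 2.75 in PSG2, 1.78 in GP6, -0.9996 in FRG2C, -1.74 in CXCL3 and -3.62 in CXCL8. Among published targets it differed by -0.44 in MCL1, -1.37 in RAB5A, 1.35 in ATG4D and -2.25 in MYCN. Among proteasome genes it differed by -0.29 in PSMA4, -0.57 in PSMD6 and 0.94 in PSMB8, and control replicate 1 by 0.55 in PSMD11. In p53 targets and cell cycle genes, control replicate 4 differed by 1.06 in SFN, 0.91 in ZMAT3, -0.43 in UHRF1 and -0.35 in TPX2. In PRC2 components it differed by -0.75 in RBBP7 and -0.84 in AEBP2. In stress and other lists it differed by -0.94 in HSPA1A, 0.97 in CHAC1, 0.84 in LSS, -1.12 in RAD54L and 1.27 in CORO1A, and control replicate 1 by -0.64 in RPS23. The median signal of whole lists in control replicate 4 differed by -0.85 for G2/M, 0.69 for cholesterol and -0.53 for glycolysis genes, but these are differences between list medians, and the median difference per gene was -0.77, 0.32 and 0.06.

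The first pattern weighed was that control replicate 4 lay apart from the other control arrays. Its lower brightness did not account for this, since after quantile normalisation the median SD of its log2 differences to the other control arrays was 0.877, against 0.38 at most among those. Its slide did not either, because miR-101 replicate 3 on the same slide differed from the other miR-101 arrays by a median SD of 0.277, against 0.33 between those. The deviations of control replicate 4 were shared by different probes of the same gene (r = 0.451 across 3504 genes, which are not independent replicates, against 0.11 at most for another control array), which is consistent with a different RNA content of this sample. Whether the culture, the RNA or the sample's label differed was not tested.

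The second pattern was that rises of at least 2-fold outnumbered falls (66.7% of such calls). Control replicate 4 did not account for it, since without that array the share was 68.1% (95% interval 66.1% to 70.1%). Scaling did not account for all of it, since quantile normalisation left 58.7% (56.4% to 61.0%). Among genes above the median signal the share was 40.3% (36.1% to 44.5%; 220 rises and 326 falls), and below it were 1006 rises and 285 falls, so that the excess lay in dim probes, which may reflect how far a dim gene can still fall above background.

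The third pattern was the rise of the NF-kB and inflammatory genes (median 1.34). All arrays are labelled as U2OS cells, a cultured line, but the marker values alone do not exclude blood or immune cells as a source. The median of their markers was 0.228 (quartiles -0.21 to 0.78), but without control replicate 4 it was 0.39 (quartiles -0.10 to 1.15), nearer to the NF-kB genes than that spread, and HBA2 (3.45) and CD14 (1.01) rose. Control replicate 4 was argued against by a median of 1.26 without it. A response to transfected RNA of any sequence would arise in both groups, since the control cells also received a synthetic RNA. Where equal in both groups, it would not give this difference. An unequal response to the synthetic RNAs stays open, and the interferon list had a median of 0.423. The design holds 1 control RNA and no mock transfection, so that such a response and repression of miR-101 targets cannot be told apart.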

How the results depend on the processing

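Array weights were chosen after the data were seen, and all other alternatives before. The count of 3583 changed genes (1457 lower, 2126 higher) moved when arrays were left out, averaged, weighted or blocked by slide. Leaving out 1 array in turn gave 1674 to 8382 changed, 605 to 3752 lower and 1069 to 4630 higher genes. Averaging control replicates 1 and 4 gave 5594 (2365 and 3229), replicates 3 and 4 5817 (2583 and 3234), and replicates 2 and 4 gave 2221 lower genes. Array weights, which gave control replicate 4 a weight of 0.0498, gave 9700 (4445 and 5255). These settings lower the share of control replicate 4 in the spread, or change the number of arrays. The slide as a block gave 1114 (323 and 791), with fewer degrees of freedom for the spread and with control replicate 3, alone on its slide, out of the estimate. Stricter thresholds gave 1653 (adjusted p under 0.01) and 1837 (log2 change of at least 1), by construction. The scaling, background, filter, probe and moderation alternatives gave 2980 to 3689 changed genes, with 1780 lower and 1909 higher after quantile normalisation and 1452 and 1560 with normexp.

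The replicate block gave 6989 genes (3058 lower, 3931 higher), and it leaves out control replicate 4, which has no partner. The numbers were not taken to pair the samples: the correlations of deviations of same-numbered arrays were 0.0066, 0.0021 and 0.12, not all above 0.1, and not every array correlated best with its own number. Under this block the proteasome list was not called (0.23, adjusted p = 0.086), and the other 4 called lists kept their calls.

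With an estimated correlation camera called 0 of the lists (5 in the main setting), at unchanged medians (targets -0.39, proteasome 0.25, heat shock 0.44, interferon 0.42, NF-kB 1.34), because that setting allows for genes that vary together. At an unadjusted p under 0.05, that setting passed 2 lists, heat shock (0.014) and NF-kB genes (0.011). Over the alternatives the adjusted p ranged from 0.00025 to 0.83 for targets and for interferon genes, from 0.00012 to 0.18 for heat shock and from 7.6e-13 to 0.18 for NF-kB genes. With fry, which compares a list with no other genes, targets (-0.39, adjusted p = 0.12) and interferon genes (0.42, adjusted p = 0.19) did not pass, while the unfolded protein response (adjusted p = 0.038), immediate early (0.031) and osteoblast lists (0.031) did. The G2/M list (0.33, adjusted p = 0.0515) was called under 14 of 23 alternatives and not under 9. Over all of them the adjusted p ranged from 0.0040 to 0.41. It was not called without control replicate 4 (0.08, adjusted p = 0.36) or with array weights (0.09, adjusted p = 0.29). Nor was it called with the replicate block (0.08, adjusted p = 0.41). These settings leave out or weight down control replicate 4, whose G2/M genes lay at -0.77. The list was also not called with median centring, with the mean of probes, or without certain single miR-101 arrays, settings that keep control replicate 4. Averaging control replicate 4 with replicate 1 or 2 did not give a call either. The proteasome list also lost its call with median centring (0.24, adjusted p = 0.071), the mean of probes (0.27, adjusted p = 0.052), control replicates 2 and 4 averaged (0.25, adjusted p = 0.063) and array weights (0.21, adjusted p = 0.063), and over its 25 alternatives the adjusted p ranged from 0.0014 to 0.83; the cause was not tested. Leaving out 1 array gave medians of 0.23 to 0.27 for it and of 0.32 to 0.68 for the interferon list. MAP1LC3B reversed to -0.054 with the mean of its probes, since its probes disagree. Of the other values of named genes under the alternatives, 2522 kept direction and side of the threshold, 312 lost a call and 110 gained one. Of the 95 called named genes 42 kept their call under every alternative and 80 under every scaling. The seed site alternatives were not run for want of transcript sequence, and trend and robust moderation gave no list value, since camera has no such setting. Signal over background limits the 123 higher and 4 lower genes given as bounds.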

Other observations

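The test of proteasome genes without POMP and that of p53 and mitosis genes in control replicate 4 were chosen after the result was seen, as were the genes named in this part. Genes that changed lay next to each other in places. The longest run held 7 neighbours that were all higher in miR-101 cells: the chemokine genes PPBP, CXCL5, CXCL3 and CXCL2, the folate enzyme gene MTHFD2L, and EREG and AREG, which encode ligands of the EGF receptor. EREG rose by 2.81 ± 0.36 and AREG by 1.70 ± 0.22 (SE, n = 4 control and 3 miR-101 arrays). Another run joined PTGS2, PLA2G4A, RGS18 and RGS2, where PLA2G4A encodes the phospholipase that releases the substrate of the PTGS2 enzyme and rose by 1.70 ± 0.35 (SE). A run of the receptor genes IL1R1 and IL1R2 with MAP4K4 and RFX8 was also higher, with IL1R1 at 1.67 ± 0.20 (SE), and so was one of the integrin genes ITGA1 and ITGA2 with PELO and PARP8, with ITGA1 at 1.17 ± 0.15 (SE).

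Neighbouring genes of unlike symbols were called in the same direction in 331 pairs among 15155 genes in genome order, against a median of 247 in 10000 shuffles (95% of them up to 271; one-sided permutation p = 1e-04, the smallest the shuffles can give). Over all adjacent pairs, families included, 394 were called alike against a median of 267, 291 of them higher and 103 lower. The count is consistent with neighbouring genes changing in the same direction, but it does not separate shared regulation from transcripts that run on into the next gene or from related sequences with unlike symbols.

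Without POMP, 31 of 39 proteasome genes had a log2 change above 0 and their median was 0.261. The p was 0.0035 at the preset correlation and 0.20 with an estimated one, so that a joint rise of the subunit genes beside the fall of POMP may be present but stays open.

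Control replicate 4 had p53 targets at a median of 0.998 above the other control arrays (95% of random lists of the same size from -0.29 to 0.37) and G2/M and mitosis genes at -0.77. This is consistent with a culture in which p53 targets were high and mitosis genes low, in 1 array whose origin the labels do not describe further. Of the 25 lists, 11 lay outside the range of 95% of random lists, among them the epithelial markers (0.92), the BCL2 family (0.72) and interferon genes (0.67), so that a difference in cell type stays open as well. The single genes farthest from the other control arrays were MAGEA10 (6.71), CD86 (5.44), LRRN1 (-4.96), LRRC2 (4.93) and NALF2 (4.65), on 1 array each and with no test.

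Of the 35 splits of the 7 arrays into 4 and 3, only 1, the real one, gave as many genes. The real split gave 3583 genes and the highest other 1063, the split of control replicates 1 to 3 from the rest. Because 1 control sample lies on 2 arrays, the independent samples are 3 and 3, with only 10 splits, too few for any share under 0.05, so that these counts leave open whether the grouping arose by chance.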
